A study of Mus musculus with 18 samples.

How the data were processed

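Single mouse oocytes were profiled by SMART-seq2, which copies polyadenylated RNA into full-length cDNA. Per the labels' protocols, each oocyte was lysed gently, its nucleus was spun down and the supernatant went into the mRNA library, which was made with a Vazyme TruePrep kit. The deposited table of each oocyte lists 47069 Ensembl genes. It gives expected counts, TPM and FPKM, per the file headers, in the layout that RSEM writes. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.4.5, TopHat2 2.1.1, Cufflinks and the build GRCm38.p5 (mm10), with no version for Cufflinks. The tool that made the expected counts, its version and the gene annotation are not given in the sources used here. Expected counts, as deposited, split reads that map to several genes, so values of near-identical paralogs, ribosomal protein genes with many pseudogenes among them, are less certain than those of single-copy genes. TPM, as deposited by the authors, served as an alternative unit, and FPKM, as deposited, was not used. Gene symbols and GRCm38 coordinates came from GENCODE release M21 and matched 46488 of the 47069 gene identifiers.

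Groups followed the labels: cell type (GV or in vitro-matured metaphase II), age (6 weeks or 12 months) and presence of MSC. The labels give no animal, litter or culture for an oocyte. Cells are not replicates, so each group of 3 oocytes counted as 1 sample, and no test, p-value, standard error or count of changed genes was derived from the oocytes. A fit that treated single oocytes as replicates (edgeR's quasi-likelihood test, with gene set tests and splits of the samples) had been planned. It was run, with several alternatives, and its results were seen before it was set aside for this reason. The groups, comparisons, gene lists and most alternatives were fixed before the data were examined. The size measure, the percentile limits, the rule for named genes in its present form, the choice of lists to lead with and the rule for calling a value moved were chosen after the data had been seen. A comparison averaging age over the 3 kinds of oocyte was also run after the data were seen and is not reported.

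Expected counts were rounded to whole numbers. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3), and genes with too few counts were removed with filterByExpr by group, which left 12037 genes. A gene's value is the difference between 2 groups of the mean log2(CPM + 1), with a pseudocount of 1, so differences of weakly expressed genes are understated. Folds are ratios of group mean CPM. Where a group had no count, the fold is a lower bound against a floor of 3 counts per library. Where it had 1 to 3 counts, the counts are given with exact Poisson 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Precision follows depth: totals ranged from 1914072 to 9193559 counts per oocyte. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 did the rest.

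There were 11 comparisons, 8 of 2 groups and 3 that combine 4 groups (co-culture averaged over ages, and the differences between ages in the maturation and co-culture effects). Named genes had a mean of at least 20 CPM in the higher group, every oocyte of one group above every oocyte of the other, and a symbol other than a predicted gene, a Riken clone or a pseudogene. Of these the 10 largest differences in each direction were taken, or 5 for age in co-cultured oocytes and for co-cultured 12m against 6wk oocytes. The 3 combined comparisons took 5 each way by size alone. Up to 3 members of each list outside the percentile limits and 1 member of each other list were added. This gave 259 genes, of which the text names a part; some are not reported here. Gdf9, Plat, Bub1b and the single somatic genes of GV 12m oocyte 3 were chosen after their values were seen.

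For 21 gene lists (742 symbols, all matched) the median difference of the measured members was set against 10000 random lists of the same size, matched on mean expression in 60 bins. Its percentile among them describes these libraries and is no test. Lists below percentile 2.5 or above 97.5 are called outside the middle 95%. Lists of cumulus and granulosa, mesenchymal stromal, and blood and immune cell markers stood for other cells that an oocyte preparation or co-culture could hold. The score of a list in 1 oocyte is the median log2 CPM of its members. The mitochondrial share counted 37 mitochondrially encoded genes. Correlations between comparisons run across genes and were made only between comparisons that share no library. Counts of the 18 libraries were compared in pairs and no 2 libraries agreed within sampling noise.

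The computation was tested on simulated negative binomial counts with the real means and library sizes (dispersion 0.5; 12037 genes, 200 changed, 50 per fold) for each of the 8 comparisons of 2 groups. For a true log2 change of 1, medians ran from 0.724 to 1.225 over the comparisons and 38 to 47 of 50 genes had the right direction. For −1 they ran from −1.155 to −0.639 (39 to 44 of 50), for 3 from 2.725 to 3.018 (50 of 50) and for −3 from −3.083 to −2.576 (49 to 50 of 50). Of 160 simulated unchanged lists of 40 genes 9 lay outside the percentile limits, and 16 of 16 changed lists did. Simulated genes varied independently of each other and the list genes had at least 20 CPM. Members of the real lists can vary together between oocytes, so this rate need not hold for them.

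Alternatives were size factors as in DESeq2, no filter on low counts, only the groups compared, TPM, removal of mitochondrially encoded genes, differences within title prefixes, other detection limits, and leaving out each oocyte in turn. Leaving out 4 oocytes together was added after the data were seen: GV 12m oocyte 3 (granulosa markers), IVM-MII 6wk oocyte 1 and MSC-IVM-MII 6wk oocyte 1 (title prefix Y01) and MSC-IVM-MII 12m oocyte 1 (lowest depth).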

Results

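The data were mRNA profiles of single mouse oocytes, each sequenced as its own SMART-seq2 library. C57BL/6 wild-type mice of 6 weeks (6wk) and 12 months (12m) were the source, per the labels. At each age there were germinal vesicle (GV) oocytes, which are arrested before meiosis resumes, oocytes matured in vitro to metaphase II (IVM-MII), and oocytes matured in vitro to metaphase II in co-culture with MSC (MSC-IVM-MII), an abbreviation that the labels do not spell out. These made 6 groups of 3 oocytes, 18 libraries in all. Total counts per oocyte were 6317859, 9193559 and 4679473 for GV 12m, 8948887, 5404854 and 4583562 for IVM-MII 12m, and 1914072, 7369629 and 4534897 for MSC-IVM-MII 12m. At 6wk they were 3895017, 3851604 and 3096673 for GV, 4271400, 3080516 and 3504660 for IVM-MII, and 4287123, 3105405 and 3148140 for MSC-IVM-MII. The labels name no animals, so each group counted as 1 sample and no test was made between groups. Values after ± are the SD over the 3 oocytes of a group and say nothing of the spread between animals. Brackets after a summed count hold its exact Poisson 95% interval, which covers counting error only. A difference is given on the log2(CPM + 1) scale, first group minus second. CPM are relative to the scaled total of a library. Higher or lower therefore does not tell whether the amount of a transcript per oocyte rose or fell.

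Metaphase II groups averaged fewer detected genes than GV groups at both ages. At 12m, 15537 ± 724 genes had a count of at least 1 in GV oocytes, 11156 ± 818 in IVM-MII and 10307 ± 1482 in MSC-IVM-MII oocytes. At 6wk the numbers were 14005 ± 1084, 10019 ± 1552 and 11114 ± 1735, and MSC-IVM-MII 6wk oocyte 1 (13117 genes) lay above GV 6wk oocyte 3 (13046 genes). The size depended on the limit: IVM-MII minus GV was −3986 at 6wk and −4380.3 at 12m with a limit of 1 count, −2417 and −3311 with 5, and −1697 and −2529.7 with 10. With every library thinned to 1914072 counts they were 13930 ± 996, 10237 ± 719 and 9781 ± 1080 at 12m, and 13192 ± 875, 9584 ± 1296 and 10661 ± 1462 at 6wk. Mitochondrially encoded genes took 2.66 ± 0.894% of the counts in GV 12m and 2.21 ± 1.40% in GV 6wk oocytes. They took 11.1 ± 4.55% in IVM-MII 12m, 10.9 ± 2.52% in MSC-IVM-MII 12m, 8.34 ± 4.51% in IVM-MII 6wk and 6.45 ± 3.001% in MSC-IVM-MII 6wk oocytes. Across the 2000 most variable genes, the first principal component held 64.5% of the variance and separated GV from metaphase II oocytes, and the second held 10.5%. The mean correlation between oocytes was 0.849 within GV 12m and 0.889 within GV 6wk. It was 0.828 within IVM-MII 12m, 0.795 within MSC-IVM-MII 12m, 0.769 within IVM-MII 6wk and 0.853 within MSC-IVM-MII 6wk. Between IVM-MII and MSC-IVM-MII oocytes it was 0.819 at 12m and 0.830 at 6wk, so oocytes with and without co-culture were about as alike as oocytes of one group.

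**Figure D1:**
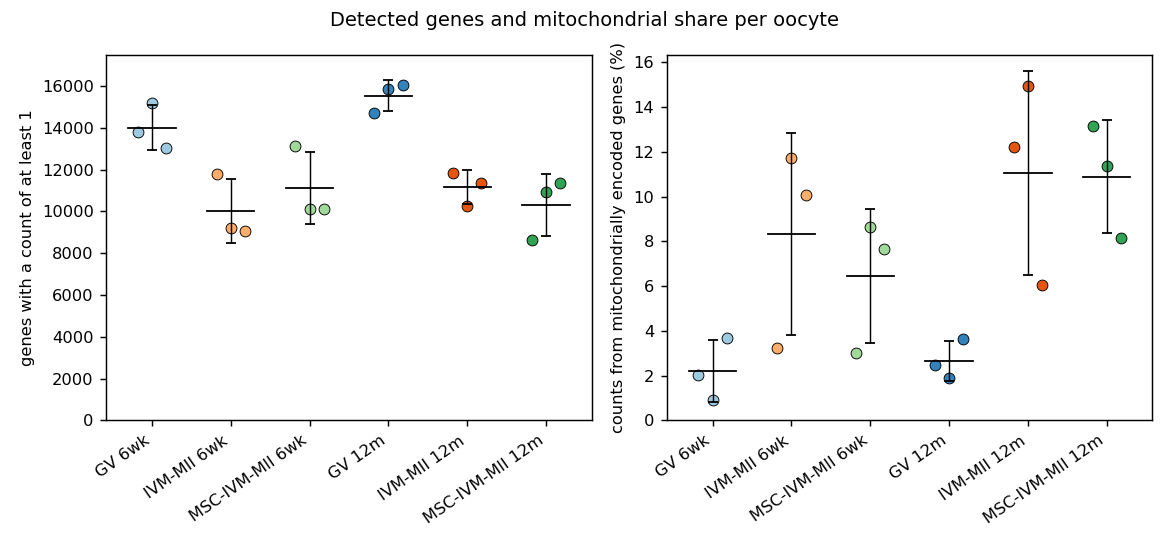
Genes with a count of at least 1 (left panel, number of genes) and the percentage of counts from mitochondrially encoded genes (right panel) in each of the 18 oocytes, by group. Points are oocytes, lines are group means and bars are the SD over 3 oocytes. GV 12m oocytes averaged 15537 genes and 2.66% mitochondrial counts, and IVM-MII 12m oocytes 11156 genes and 11.1%.

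The sample titles carry 5 prefixes that the labels do not explain, and 0 of them were shared between the ages. A difference between 12m and 6wk oocytes therefore cannot be told apart from a difference between prefixes. Among the 6wk metaphase II oocytes, IVM-MII oocyte 1 and MSC-IVM-MII oocyte 1 carried the prefix Y01 and the other 4 carried Y03. Both Y01 oocytes stood apart. Mos, the kinase that keeps metaphase II arrest, was at 1261 and 642.9 CPM in them and at no more than 12.1 CPM in the other 10 metaphase II oocytes. Gdf9, an oocyte growth factor, was at 17374 and 12657 CPM against at most 3397 CPM, and Plat, tissue plasminogen activator, at 4078 and 1967 CPM against at most 242 CPM. In the same oocytes mitochondrially encoded genes took 3.22% and 3.03% of the counts. Zp3 was at 115 and 473 CPM in these oocytes and Cdk1 at 0.23 and 7.39 CPM. A further oocyte stood apart by its somatic transcripts. GV 12m oocyte 3 held 2272 CPM of the cumulus and granulosa cell markers, against 156 to 423 CPM in the other 5 GV oocytes, with Inha, an inhibin subunit, at 917 CPM and Gja1, the gap junction protein of granulosa cells, at 674 CPM. Of the 29 markers 16 were highest in this oocyte. Cyp19a1 (16.2 CPM, against 19.8 to 33.0 CPM in the other 5) and Cyp11a1 (0.15 CPM) were not raised.

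**Figure D2:**
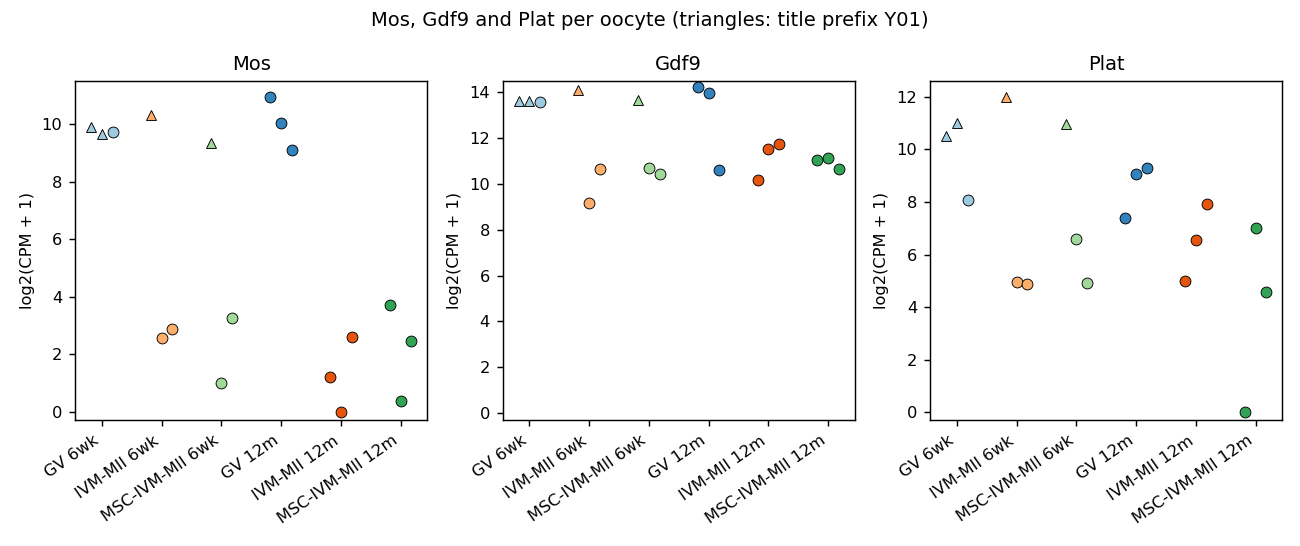
CPM of Mos, Gdf9 and Plat in each of the 18 oocytes by group, on a log axis. Each point is an oocyte and triangles mark the oocytes with title prefix Y01. In the Y01 oocytes of the 6wk metaphase II groups Mos was at 1261 and 642.9 CPM, and in the other 10 metaphase II oocytes at no more than 12.1 CPM.

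The comparison of IVM-MII with GV oocytes at 6wk asked which transcripts differ after maturation in vitro. Each library was made from the supernatant after the nucleus was spun down. GV values may therefore lack RNA held in the nucleus, and this step may act differently on metaphase II oocytes. Its effect on the maturation differences at either age was not tested. Among the single genes with the largest differences, Zp3, Gja4 and Cdk1 were lower in IVM-MII oocytes. Zp3, a zona pellucida glycoprotein, was at 80.4 ± 34.9 CPM against 9309 ± 3583 CPM in GV oocytes, 116-fold lower, from 940 [881–1002] against 94401 [93800–95005] counts. Gja4, the gap junction protein that couples the oocyte to granulosa cells, was 106-fold lower (8.73 ± 14.9 against 927 ± 92.2 CPM). Cdk1, the kinase that drives entry into M phase, had 17 [9.9–27.2] against 4033 [3910–4159] counts. Higher in IVM-MII oocytes were Lin7c, a PDZ scaffold protein (175 ± 36.2 against 10.9 ± 5.25 CPM, 16.1-fold), and Esco1, an acetyltransferase of cohesin (157 ± 57.4 against 18.6 ± 23.1 CPM, 8.45-fold). In GRCm38 coordinates these protein-coding genes are Zp3 (ENSMUSG00000004948, chromosome 5, 135980099 to 135988624), Gja4 (ENSMUSG00000050234, chromosome 4, 127311421 to 127314039), Cdk1 (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938), Lin7c (ENSMUSG00000027162, chromosome 2, 109890853 to 109901003) and Esco1 (ENSMUSG00000024293, chromosome 18, 10566507 to 10610352).

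Lists of genes moved as groups in this comparison. The median of all 12037 genes was −0.52, and list medians are to be read against it. Cytosolic ribosomal protein mRNAs were lower for 78 of 79 members, with a median of −4.15 that lay below all 10000 random lists of matched expression. Rps4x was at 4.42 ± 3.41 against 454 ± 196 CPM. Nuclear-encoded oxidative phosphorylation mRNAs were lower for 71 of 76 members (median −3.61, also below all random lists), among them Ndufa9 of complex I (2.81 against 404.1 CPM). Proteasome mRNAs were lower for 27 of 35 (median −2.16, percentile 0.0), with the ATPase subunit gene Psmc2 at 3.10 ± 3.46 against 472 ± 172 CPM. Of 29 oocyte and maternal effect genes, 19 were lower and 10 higher (median −0.69, percentile 0.46). Figla, a transcription factor of zona genes, had 1 [0.0–5.6] against 1123 [1058–1191] counts, and Khdc3 of the subcortical maternal complex was at 38.0 against 1584 CPM. All 13 mitochondrially encoded mRNAs were higher (median 1.79, percentile 99.91), for example mt-Atp8 at 253 ± 169 against 38.7 ± 22.7 CPM. Cohesin and chromosome cohesion genes were higher for 17 of 24 (median 1.12, percentile 99.98). Deadenylation, decay and translational control genes (median 0.55, percentile 98.96) and DNA methylation and histone modifier genes (median 0.33, mean −0.02, percentile 98.38) are given no direction, since both medians turned without IVM-MII oocyte 1. Among their members Pabpc1l, an oocyte poly(A)-binding protein, was at 2.82 against 88.0 CPM and Dnmt3l, a cofactor of DNA methylation, at 19.8 against 281 CPM.

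The other lists lay within the middle 95% of random lists. Their medians were 0.30 for the meiotic cell cycle (mean −0.34), 0.15 for DNA damage response (mean −0.34), 0.22 for PI3K-AKT-mTOR, −0.08 for TGF-beta and BMP, −0.21 for blood and immune cell, −0.28 for sterol synthesis and −0.38 for apoptosis genes. They were −0.58 for antioxidant, −0.76 for autophagy and lysosome, −0.79 for chaperone and −1.02 for glycolysis genes. Markers of other cell types were lower for 9 of 11 measured cumulus and granulosa genes (median −1.29) and for 7 of 9 measured mesenchymal genes (median −0.90). Single oocytes moved several lists: without IVM-MII oocyte 1, of prefix Y01, the proteasome median was −1.14, deadenylation −0.125, DNA methylation −0.13 and cohesin 0.445. Without GV oocytes 1, 2 and 3 in turn cohesin was 0.61, 2.20 and 0.60 and DNA methylation 0.21, 0.72 and 0.01, without GV oocytes 2 and 3 deadenylation was 1.015 and 0.25 and the oocyte genes −0.36 and −1.04, and without IVM-MII oocyte 2 cohesin was 1.92 and DNA methylation 0.71. The GV group held 2 Y01 and 1 Y03 oocytes and the IVM-MII group 1 and 2. Within title prefixes cohesin was 1.79, DNA methylation 0.60, PI3K-AKT-mTOR 0.91, meiotic 0.65, DNA damage 0.48, chaperones −0.41, granulosa markers −0.74, mesenchymal markers −1.35 and blood and immune markers −0.01, while TGF-beta and sterol genes turned to 0.52 and 0.05.

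The same comparison was made at 12m. Mos was 556-fold lower in IVM-MII than in GV oocytes (2.14 ± 2.64 against 1192 ± 723 CPM; 35 [24.4–48.7] against 20864 counts). Rpl3, a ribosomal protein of the large subunit, had no count in IVM-MII oocytes against 193 ± 87.1 CPM in GV oocytes, at least 362-fold lower at a floor of 3 counts per library. Slbp, which binds the stem-loop of histone mRNAs, was 8.40-fold higher (6395 ± 1814 against 761 ± 342 CPM). Mos (ENSMUSG00000078365) lies on chromosome 4 from 3870657 to 3872105 and Slbp (ENSMUSG00000004642) on chromosome 5 from 33634952 to 33652574.

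Ribosomal protein mRNAs were lower for 78 of 79 members at 12m (median −4.26) and oxidative phosphorylation mRNAs for 72 of 76 (median −2.85), against a median of all genes of −0.52. Both medians lay below all random lists, as did that of the proteasome genes (30 of 35 lower, median −1.70). Rps27a was at 1.55 against 467 CPM and Atp5o, an ATP synthase subunit gene, at 4.85 against 578 CPM. Antioxidant and redox genes were lower for 27 of 34 (median −1.51, percentile 0.11), with Gpx4, the peroxidase that reduces lipid peroxides, at 11.7 against 403.05 CPM and Glrx, a glutaredoxin, at 117 against 1397 CPM. Glycolysis genes were lower for 15 of 23 (median −1.30, percentile 1.89). Tpi1 was at 19.4 against 232 CPM, Aldoa at 36.2 against 375 CPM, and Ldha had 2 [0.2–7.2] against 3103 counts. Oocyte and maternal effect genes were lower for 17 of 29 (median −0.99, percentile 0.02), with Zp3 at 160 against 10256 ± 9571 CPM. Mitochondrially encoded mRNAs were higher for 12 of 13 and lower for 0 (median 1.46, percentile 97.21). Markers of other cell types lay within the middle 95% of random lists, with medians of −1.11 for cumulus and granulosa (−2.23 to −0.73 with an oocyte left out), −0.86 for mesenchymal (−1.06 to −0.27) and −0.61 for blood and immune cell markers (−0.78 to −0.49). Within title prefixes the medians were −3.95 for ribosomal proteins and −2.42 for oxidative phosphorylation at 12m, and −4.51 and −3.96 at 6wk. Cohesin genes, with a median of 1.12 at 6wk, had 0.42 at 12m, which turned to −0.15 within title prefixes. Across all 12037 genes the maturation differences at the 2 ages correlated with Pearson's r of 0.798 and Spearman's rho of 0.766, and 78.9% of genes had the same direction; genes are not independent replicates. Without GV 12m oocyte 2 the oocyte gene median was −0.50, and without GV 12m oocyte 3, which held the granulosa transcripts, the glycolysis median was −0.72.

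**Figure D3:**
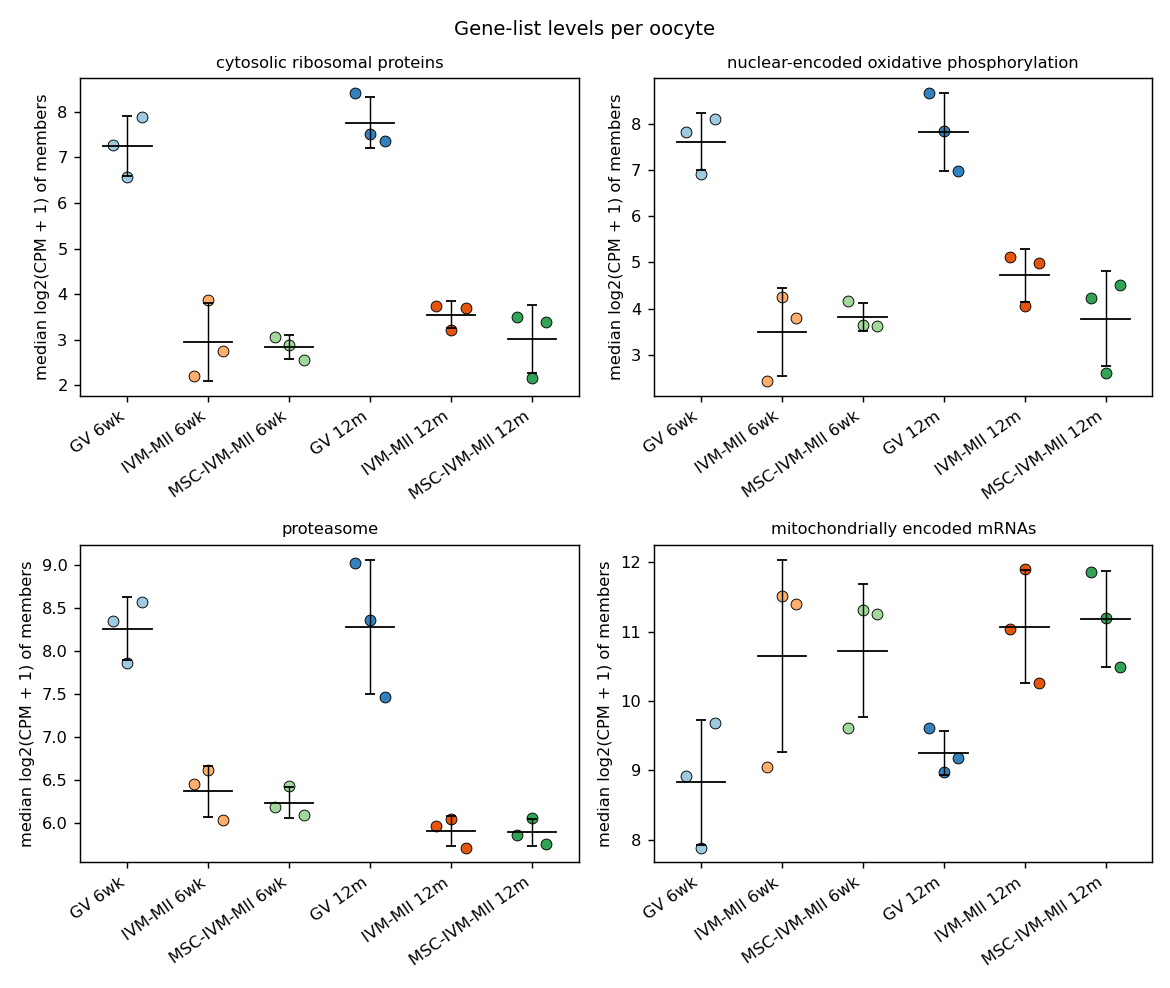
Median log2 CPM of the members of 4 gene lists (ribosomal proteins, nuclear-encoded oxidative phosphorylation, proteasome, mitochondrially encoded mRNAs) in each of the 18 oocytes, by group. Points are oocytes, lines are group means and bars are the SD over 3 oocytes. The ribosomal protein score was 7.24 ± 0.661 in GV 6wk and 2.94 ± 0.852 in IVM-MII 6wk oocytes, and 7.76 ± 0.569 and 3.54 ± 0.295 at 12m.

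GV oocytes of 12m were compared with those of 6wk for differences with age before maturation. Bicd1, a dynein adaptor, was at 20.2 ± 3.18 CPM at 12m (374 counts) and had no count at 6wk, at least 23.3-fold higher. Dnajb14, a J-domain co-chaperone of the endoplasmic reticulum, was 8.22-fold lower at 12m (43.6 ± 7.81 against 358 ± 243 CPM). Prl8a2, of the prolactin family, was at 5.39 against 32.2 CPM and Calb1, a calcium-binding protein, at 6.02 against 31.7 CPM. Single oocyte genes went both ways. Lower at 12m were Oog4 (288 against 1110.2 CPM), Astl, the protease that cleaves Zp2 (113 against 457 CPM), Tle6 of the subcortical maternal complex (608 against 1504 CPM) and Zp1 (913 against 1859 CPM), while of 19 Oog, Nlrp and Oosp genes, a family chosen after the data were seen, 13 were higher (median 0.56, 0.39 to 0.55 with an oocyte left out). Tacc3, a spindle protein, was at 335 against 1294 CPM. The genes are annotated on GRCm38 as Bicd1 (ENSMUSG00000003452, chromosome 6, 149408886 to 149563329), Dnajb14 (ENSMUSG00000074212, chromosome 3, 137867675 to 137916557), Prl8a2 (ENSMUSG00000018259, chromosome 13, 27345673 to 27354216) and Calb1 (ENSMUSG00000028222, chromosome 4, 15881264 to 15908064), all protein coding.

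Against a median of all genes of 0.12, ribosomal protein mRNAs were higher at 12m for 78 of 79 members (median 0.58, percentile 100.0), with Rpl29 at 169 against 76.9 CPM. Deadenylation, decay and translational control genes were higher for 26 of 35 (median 0.52, percentile 99.99) and TGF-beta and BMP genes for 16 of 22 (median 0.48, percentile 98.77). Chaperone genes were lower for 21 of 35 (median −0.20, percentile 0.71), among them the disulfide isomerase gene Pdia3 (109 against 229 CPM). GV 12m oocyte 3 moved with these groups: its cumulus and granulosa markers stood at 2272 CPM, and 8 of 11 measured markers were higher in the 12m group (median 0.61, percentile 95.95). Without that oocyte the deadenylation median was 0.175 and the TGF-beta median 0.10. Without GV 12m oocyte 1 the medians were 0.27 for ribosomal proteins, 0.92 for deadenylation and 0.74 for TGF-beta, and without GV 12m oocyte 2 that of chaperones was −0.32. Without GV 6wk oocytes 1, 2 and 3 in turn TGF-beta was 0.26, 1.03 and 0.14, without oocytes 2 and 3 ribosomal proteins were 0.125 and 0.915, and without oocyte 3 deadenylation was 0.25 and chaperones −0.42. For 5 further lists outside the middle 95% of random lists no direction is given, since it turned with a single oocyte left out. These were oxidative phosphorylation (median 0.21, −0.25 to 0.63 with an oocyte left out), mitochondrially encoded (0.385, −0.08 to 0.85), PI3K-AKT-mTOR (0.395, −0.05 to 0.76), glycolysis (0.375, −0.24 to 0.53) and oocyte and maternal effect genes (−0.19, −0.39 to 0.36).

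IVM-MII oocytes of 12m were set against those of 6wk in the same way. Tmem214 was at 30.1 ± 7.98 CPM at 12m and had no count at 6wk, at least 36.7-fold higher. Akap2, which anchors protein kinase A, was 24.6-fold higher (72.3 ± 26.1 against 2.94 ± 0.193 CPM), Trim15 was at 44.3 against 1.80 CPM, and Parn, a poly(A) ribonuclease, at 23.7 against 0.950 CPM. Dnajb14 was 18.8-fold lower (39.2 ± 18.8 against 736 ± 382 CPM) and Prl8a2 was at 6.54 against 41.8 CPM, both in the direction seen in GV oocytes. Gclm, of glutathione synthesis, was at 7.26 against 57.8 CPM, and Nsdhl, of sterol synthesis, was higher (22.0 against 1.20 CPM). Id3, a target of BMP signalling, was at 19.4 CPM at 12m with no count at 6wk, at least 23.6-fold higher. Tmem214 (ENSMUSG00000038828) lies on chromosome 5 from 30868012 to 30879180, Akap2 (ENSMUSG00000038729) on chromosome 4 from 57717657 to 57896984, and Trim15 (ENSMUSG00000050747) on chromosome 17 from 36860691 to 36867210.

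The median of all genes was 0.16. Oxidative phosphorylation mRNAs were higher at 12m for 65 of 76 members (median 0.795, percentile 100.0), among them Ndufv3 (7.96 against 1.11 CPM). Ribosomal protein mRNAs were higher for 60 of 79 (median 0.58, percentile 99.97), with Rpl39 at 17.5 against 1.30 CPM. Mitochondrially encoded mRNAs (median 0.59, percentile 98.12) are given no direction, since the median turned with a single oocyte left out, and mt-Nd4l had no count at 12m against 5.06 CPM at 6wk, at least 9.48-fold lower. IVM-MII 6wk oocyte 1, of prefix Y01 and with 3.22% mitochondrial counts, moved with these groups: without it the medians were 0.31 for oxidative phosphorylation, 0.16 for ribosomal proteins and −0.26 for mitochondrial mRNAs. Without IVM-MII 6wk oocyte 2 the ribosomal protein median was 1.09, and without IVM-MII 12m oocytes 1 and 2 in turn the mitochondrial median was 0.39 and 0.15. Across genes the age differences of GV and IVM-MII oocytes correlated at 0.083 (Spearman 0.073) and 53.2% of genes had the same direction, and the correlation lay between 0.012 (without IVM-MII 12m oocyte 1) and 0.161 (without GV 12m oocyte 3) with an oocyte left out.

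Among co-cultured oocytes, Dnajb14 was again lower at 12m (30.1 ± 15.8 against 353 ± 205 CPM, 11.8-fold), as were Prl8a2 (5.42 against 23.0 CPM) and Calb1 (1.98 against 44.3 CPM). H1foo, the oocyte linker histone, was at 3756 ± 3514 against 13768 ± 4615 CPM. Of single genes of cell division, Ndc80 of the kinetochore was lower at 12m, at 23.4 against 133 CPM. So were Cdc20, an activator of the anaphase-promoting complex (120.0 against 465 CPM), and the spindle kinase gene Aurka (126 against 268 CPM). Higher at 12m were Akap2 (66.6 against 4.42 CPM), Cgref1 (25.0 against 1.03 CPM) and Snhg14 (44.8 against 3.03 CPM). H1foo (ENSMUSG00000042279) lies on chromosome 6 from 115944938 to 115950236.

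As a group, meiotic cell cycle and spindle checkpoint genes were lower at 12m for 29 of 36 members (median −0.52, percentile 0.23), sterol synthesis genes for 17 of 19 (median −0.64, percentile 1.14) and proteasome genes for 22 of 35 (median −0.58, percentile 0.04). The median of all genes was −0.12. Mitochondrially encoded mRNAs (median 0.56, percentile 99.98) are given no direction, since the median turned with 2 oocytes left out together. No direction is given for ribosomal protein (median 0.12, −0.03 to 0.64 with an oocyte left out) and TGF-beta genes (0.30, −0.14 to 0.485), whose medians turned with a single oocyte left out. Leaving out MSC-IVM-MII 12m oocyte 1, which had the lowest depth, together with MSC-IVM-MII 6wk oocyte 1, of prefix Y01, gave a mitochondrial median of −0.02. Left out singly, MSC-IVM-MII 12m oocyte 1 gave −0.31 for meiotic and −0.23 for sterol genes, oocyte 2 −0.25 for the proteasome and −1.03 for sterol genes, and oocyte 3 −0.97 for sterol genes and 1.00 for mitochondrial mRNAs; MSC-IVM-MII 6wk oocytes 1, 2 and 3 gave 0.11, 1.01 and 0.86 for mitochondrial mRNAs, and oocytes 1 and 2 −0.32 and −0.38 for the proteasome. Age differences in co-cultured oocytes correlated across genes at 0.117 with those in GV oocytes (Spearman 0.095, 51.0% in the same direction). This was 0.070, 0.065, 0.044 and 0.077 without GV 12m oocyte 1, GV 6wk oocyte 2, MSC-IVM-MII 12m oocyte 2 and MSC-IVM-MII 6wk oocyte 2 in turn, and −0.013 without the 4 oocytes that stood apart by prefix, granulosa markers or low depth. With those in IVM-MII oocytes they correlated at 0.144 (Spearman 0.121, 52.4%), and at 0.088, 0.092, 0.219 and 0.051 without IVM-MII 12m oocyte 2, IVM-MII 6wk oocyte 1, MSC-IVM-MII 12m oocyte 2 and MSC-IVM-MII 12m oocyte 3 in turn.

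Co-cultured oocytes of 12m were compared with IVM-MII oocytes of 12m for differences that go with MSC. Tet1, a dioxygenase that oxidises 5-methylcytosine, was at 19.6 ± 5.62 against 0.708 ± 1.23 CPM, from 269 [237.8–303.1] against 10 [4.8–18.4] counts. Atp6v1a, a subunit gene of the vacuolar proton pump, was at 56.0 ± 27.7 against 11.4 ± 8.39 CPM. Ust, a uronyl sulfotransferase, was at 42.9 against 5.28 CPM and Lrba, of vesicle trafficking, at 24.8 against 3.27 CPM. Lower after co-culture were Samm50, of mitochondrial outer membrane assembly (5.87 against 24.9 CPM), and Egfr, the epidermal growth factor receptor (8.85 against 41.1 CPM, a difference of −2.70 that was −1.45 without MSC-IVM-MII 12m oocyte 1). Tet1 (ENSMUSG00000047146) lies on chromosome 10 from 62804570 to 62908996, Atp6v1a (ENSMUSG00000052459) on chromosome 16 from 44085402 to 44139705 and Egfr (ENSMUSG00000020122) on chromosome 11 from 16752203 to 16918158.

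Oxidative phosphorylation mRNAs were lower in co-cultured 12m oocytes for 63 of 76 members (median −0.63, percentile 0.0), with Ndufv3 at 0.713 against 7.96 CPM, Atp5g1 at 8.59 against 26.4 CPM and Uqcrq at 4.27 against 12.7 CPM. Ribosomal protein mRNAs were lower for 59 of 79 (median −0.49, percentile 0.06), among them Rpl5 (1.38 against 9.02 CPM) and Rpl39 (3.15 against 17.5 CPM). The same IVM-MII 12m oocytes enter the comparison by age, where both lists were higher at 12m. High values in these oocytes alone would give opposite signs in both comparisons, so the lower medians here are not independent of that result. PI3K-AKT-mTOR genes were higher for 17 of 30 (median 0.46, percentile 99.96). TGF-beta and BMP genes (median 0.37, percentile 98.06) and the 9 measured mesenchymal stromal cell markers (median −0.745, percentile 1.97) are given no direction, since each median turned with a single oocyte left out. Of these markers 5 were lower and 3 higher, with Sparc at 5.98 against 0.188 CPM (a difference of 2.01 that was 1.21 without MSC-IVM-MII 12m oocyte 2) and Mmp2 at 52.1 against 96.7 CPM. Mitochondrially encoded mRNAs had a median of −0.02 (mean 0.10). Within title prefixes the medians were −0.65 for oxidative phosphorylation, −0.57 for ribosomal proteins and 0.42 for mitochondrially encoded mRNAs. Without MSC-IVM-MII 12m oocytes 1 and 2 in turn, oxidative phosphorylation was −0.995 and −0.105, ribosomal proteins −0.84 and −0.22, PI3K-AKT-mTOR 0.71 and 0.03, TGF-beta 0.66 and −0.01 and the mesenchymal markers −0.22 and −0.30. Without MSC-IVM-MII 12m oocyte 3 TGF-beta was 0.65, without IVM-MII 12m oocyte 1 the mesenchymal median was 0.01, and without IVM-MII 12m oocytes 2 and 3 PI3K-AKT-mTOR was 0.16 and 0.09. Across genes the co-culture difference at 12m correlated at 0.004 with the age difference in GV oocytes (Spearman 0.003, 46.6% in the same direction, −0.133 to 0.109 with an oocyte left out and −0.182 without the 4 oocytes that stood apart by prefix, granulosa markers or low depth).

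At 6wk, co-cultured oocytes had higher Cphx2, a homeobox gene (42.9 ± 25.5 against 2.47 ± 3.04 CPM), Nsdhl (25.9 ± 15.9 against 1.20 ± 2.08 CPM) and Itgb3, an integrin (21.4 ± 1.51 against 3.21 ± 3.63 CPM), than IVM-MII oocytes. Lmbrd1, which takes part in the export of cobalamin from lysosomes, was lower (4.88 ± 6.03 against 41.5 ± 25.1 CPM), as was Nfyb, a subunit of the transcription factor NF-Y (39.1 against 88.8 CPM). Nsdhl (ENSMUSG00000031349) lies on chromosome X from 72918557 to 72958514, Itgb3 (ENSMUSG00000020689) on chromosome 11 from 104608000 to 104670476 and Lmbrd1 (ENSMUSG00000073725) on chromosome 1 from 24678630 to 24766301. Deadenylation, decay and translational control genes were higher for 29 of 35 members (median 0.54, percentile 99.18, against 0.20 for all genes), with Msi2, an RNA-binding protein, at 15.8 against 3.44 CPM. The terminal uridylyltransferase genes of that list were lower: Tut7 was at 39.7 ± 4.16 against 67.3 ± 6.42 CPM, and Tut4 had no count against 3.38 CPM, at least 3.80-fold lower. Without IVM-MII 6wk oocyte 2 and MSC-IVM-MII 6wk oocyte 2 in turn the deadenylation median was 0.09 and 0.91. Markers of other cell types lay within the middle 95% of random lists, with medians of 0.48 for mesenchymal (0.17 to 0.82 with an oocyte left out, 0.00 without a filter on low counts), 0.00 for granulosa and 0.12 for blood and immune cell markers. No direction is given for 4 further lists outside the middle 95% of random lists. Mitochondrially encoded mRNAs (median −0.33, −1.10 to 0.29 with an oocyte left out), ribosomal protein mRNAs (−0.06, −0.65 to 0.22) and proteasome genes (−0.05, −0.41 to 0.05) turned with a single oocyte left out, and antioxidant genes (−0.12) came to 0.00 without IVM-MII 6wk oocyte 2. Both groups held 1 Y01 and 2 Y03 oocytes, and the lowest of these mitochondrial values was that without the Y01 oocyte of the IVM-MII group and the highest that without the Y01 oocyte of the MSC-IVM-MII group. Across genes the co-culture differences at 6wk and 12m correlated at 0.014 (Spearman 0.024), 48.3% had the same direction, and the correlation lay between −0.08 and 0.125 with an oocyte left out and was 0.176 without the 4 oocytes that stood apart.

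Co-cultured oocytes of 12m were also set against IVM-MII oocytes of 6wk, which asks how near co-cultured 12m oocytes came to 6wk oocytes. The IVM-MII 6wk oocytes also enter the comparison by age without co-culture, so the 2 comparisons are not independent. Dnajb14 was at 30.1 against 736 CPM, Prl8a2 at 5.42 against 41.8 CPM, Akap2 at 66.6 against 2.94 CPM and Trim15 at 36.0 against 1.80 CPM. Stim2, a calcium sensor of the endoplasmic reticulum, was at 2.86 against 46.1 CPM. TGF-beta and BMP genes were higher for 17 of 22 members (median 0.70, percentile 99.32), with Id3 at 11.1 CPM against no count, at least 13.5-fold higher, Ski at 74.1 against 28.9 CPM and Bmp6 at 13.7 against 6.24 CPM. Proteasome genes were lower for 28 of 35 (median −0.38, percentile 0.1). Ribosomal protein (median 0.18, percentile 75.47) and oxidative phosphorylation mRNAs (median −0.05, mean 0.02, percentile 11.54) lay within the middle 95% of random lists. Without IVM-MII 6wk oocytes 1 and 2 in turn the TGF-beta median was 1.40 and 0.36, and without MSC-IVM-MII 12m oocytes 2 and 3 the proteasome median was −0.10 and −0.59.

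Averaged over both ages, co-culture went with lower ribosomal protein (59 of 79 lower, median −0.38), oxidative phosphorylation (60 of 76 lower, median −0.34) and proteasome mRNAs (25 of 35 lower, median −0.23), at percentiles 0.0, 0.0 and 0.26. By age the ribosomal protein median was −0.49 at 12m and −0.06 at 6wk, and that of oxidative phosphorylation −0.63 at 12m and 0.10 at 6wk. TGF-beta and BMP genes were higher for 18 of 22 (median 0.49, percentile 99.74), and PI3K-AKT-mTOR genes for 19 of 30 (median 0.37, percentile 99.53). Among the named genes Lzts1 had the largest positive difference (2.92), from 41.3 to 230.0 CPM with co-culture at 12m and from 112 to 191 CPM at 6wk. Tpp1, a lysosomal peptidase, was at 20.5 without and 5.71 CPM with co-culture at 12m, and at 25.8 and 10.4 CPM at 6wk, a 6wk difference of −1.42 that was −0.91 without MSC-IVM-MII 6wk oocyte 3. Without MSC-IVM-MII 12m oocyte 2 the oxidative phosphorylation median was −0.01 and the ribosomal protein median −0.14; without IVM-MII 6wk oocytes 1 and 2 in turn oxidative phosphorylation was −0.69 and −0.14 and the proteasome −0.43 and −0.09, without IVM-MII 6wk oocyte 2 ribosomal proteins were −0.20, and without IVM-MII 12m oocyte 1 oxidative phosphorylation was −0.20. Without IVM-MII 6wk oocyte 1 PI3K-AKT-mTOR was 0.64, without MSC-IVM-MII 6wk oocyte 1 it was 0.16 and TGF-beta 0.25. Cohesin genes had a median of 0.39 that was 0.003 without MSC-IVM-MII 12m oocyte 2, 0.03 without IVM-MII 6wk oocyte 2, 0.16 without MSC-IVM-MII 6wk oocyte 1, and 0.25 and 0.21 without IVM-MII 12m oocytes 2 and 3.

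The difference between ages in the maturation effect was taken as the 12m difference minus the 6wk difference. Mos had −4.24, at 1192 in GV and 2.14 CPM in IVM-MII oocytes of 12m and at 867 and 424 CPM at 6wk, where IVM-MII oocyte 1 held nearly all of it (−1.85 without it). Fndc3b had −5.05 (29.6 and 0.30 CPM at 12m, 4.29 and 17.1 CPM at 6wk). Eif4g2, a translation initiation factor, had −4.35 (84.3 and 17.2 CPM at 12m, 17.1 and 39.98 CPM at 6wk). The ribosomal protein median was −0.06 (percentile 6.01). Antioxidant genes had −0.32 (20 of 34 lower, percentile 1.97; −0.61 without IVM-MII 6wk oocyte 1). No direction is given for mesenchymal markers, which had a median of 1.12 (percentile 99.64) and of −0.27 without a filter on low counts. Nor is one given for 5 further lists outside the middle 95% of random lists, whose medians turned without the 4 oocytes that stood apart by prefix, granulosa markers or low depth. These were oxidative phosphorylation (0.56, then −0.21), PI3K-AKT-mTOR (−0.43, then 0.33), DNA methylation and histone modifier (−0.40, then 0.09), cohesin (−0.34, then 0.64) and deadenylation genes (−0.27, then 0.58).

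The co-culture effect at 12m minus that at 6wk was lower for oxidative phosphorylation mRNAs (60 of 76, median −0.78, percentile 0.01, against −0.305 for all genes) and for oocyte and maternal effect genes (23 of 29, median −0.64, percentile 1.60). Mesenchymal markers (median −1.41, percentile 0.53) are given no direction, since the median was 0.49 without the 4 oocytes that stood apart. Of the named genes Lmbrd1 had the largest positive value, 4.98, from 6.14 without to 14.2 CPM with co-culture at 12m and from 41.5 to 4.88 CPM at 6wk. Cphx3, a homeobox gene like Cphx2, had −6.88, from 53.8 to 5.08 CPM at 12m and from 0.460 to 75.0 CPM at 6wk. Without MSC-IVM-MII 12m oocyte 2 and IVM-MII 6wk oocyte 1 in turn the oxidative phosphorylation median was −0.17 and −0.41, and without IVM-MII 12m oocyte 3, IVM-MII 6wk oocyte 2 and MSC-IVM-MII 6wk oocyte 1 in turn the oocyte gene median was −0.24, −0.365 and −0.295. Without IVM-MII 12m oocyte 1 and IVM-MII 6wk oocyte 1 in turn the mesenchymal median was −0.92 and −0.32. No direction is given for mitochondrially encoded (median 0.45, −0.195 to 1.09 with an oocyte left out) and antioxidant genes (0.23, −0.015 to 0.41), which turned with a single oocyte left out.

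**Figure D4:**
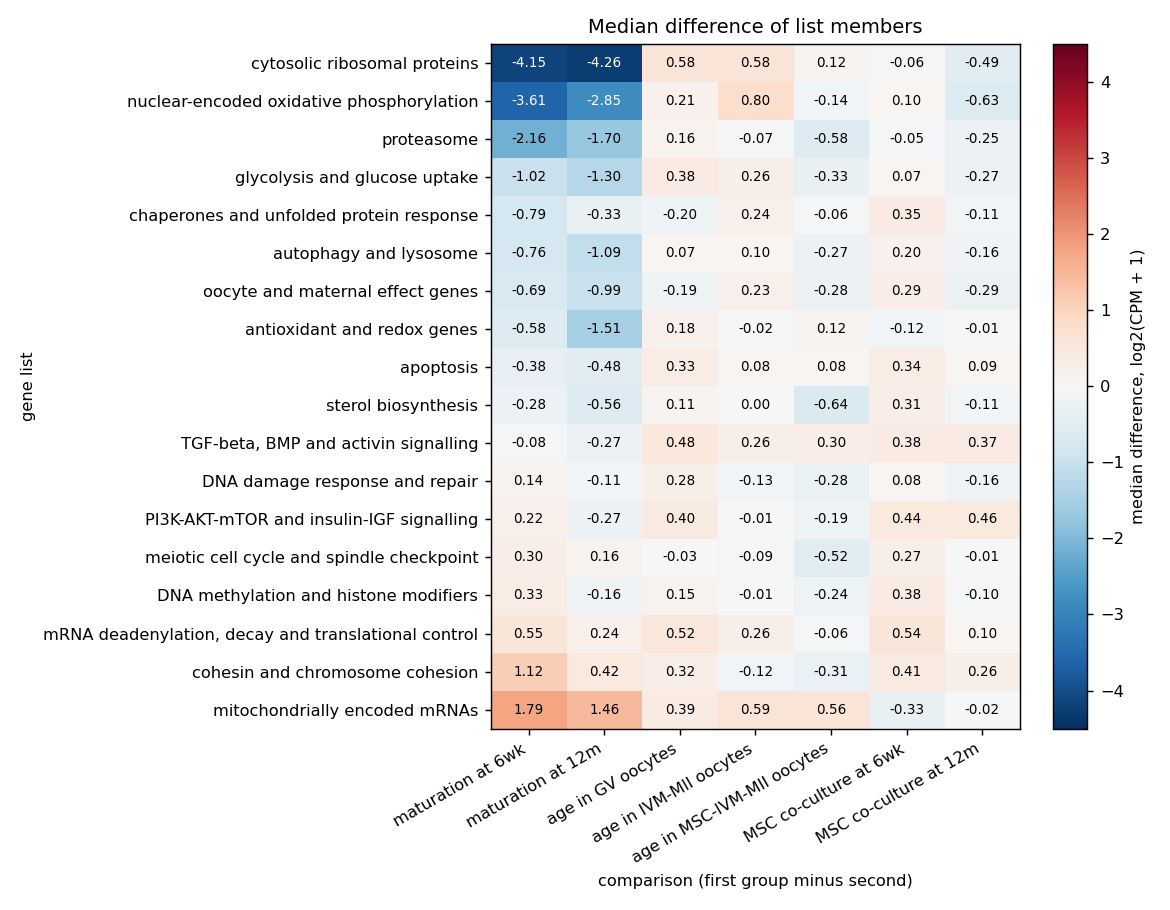
Median difference in log2(CPM + 1), first group minus second, of the members of 18 gene lists (vertical axis) in 7 comparisons (horizontal axis), with colour giving the size and direction. Each cell is the median over the list's measured genes. Ribosomal protein genes reached −4.15 and −4.26 in the 2 maturation comparisons and 0.58 in GV and in IVM-MII oocytes compared by age.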

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

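No test was made in this part, and the difference between the paired comparisons was not tested for any gene. The 259 named genes, chosen after the data were seen, and 24 lists and measures were searched over 3 pairs of comparisons (co-culture at each age, maturation at each age, and age in GV and in IVM-MII oocytes). A result is given where every oocyte of one group lay above every oocyte of the other in one comparison and every oocyte lay below in its partner. This held for 4 genes and for 0 lists or measures. With 3 oocytes per group, the order of the oocytes alone can give such a pattern in some of 259 genes. Many of these genes had also been named because their oocytes did not overlap. The number to be met by chance was not computed, so the 4 genes are no evidence of opposite effects. CPM values here are group means on the log scale turned back to CPM.

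With co-culture, Nlrp9a, an oocyte gene of the NLRP family, was lower at 12m (39.1 against 78.3 CPM, a log2 difference of −0.98) and higher at 6wk (61.5 against 33.7 CPM, 0.85). Psmb6, a catalytic subunit gene of the proteasome, was lower with co-culture at 12m (142 against 263 CPM, −0.89) and higher at 6wk (236 against 150.1 CPM, 0.65, and 0.37 without IVM-MII 6wk oocyte 2). Itgb3 was lower with co-culture at 12m (8.97 against 30.3 CPM, −1.65) and higher at 6wk (21.4 against 2.05 CPM, 2.87). Itgb3 also went opposite ways with maturation, higher in IVM-MII than GV oocytes at 12m (30.3 against 12.1 CPM, 1.25) and lower at 6wk (2.05 against 9.88 CPM, −1.84), so the IVM-MII groups enter both of its results. Gclm, the modifier subunit of glutamate-cysteine ligase, was lower in IVM-MII oocytes at 12m (6.99 against 25.8 CPM, −1.74) and higher at 6wk (55.2 against 16.9 CPM, 1.65).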

How the results depend on the processing

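Leaving out 4 oocytes together was chosen after the data were seen, as were all alternatives for the correlations and the limits by which a value counts as moved. The other alternatives had been listed in advance. The DESeq2 Wald test, limma, fry and an estimated correlation between genes were run with oocytes as replicates, seen and set aside, and are not reported. No paired analysis by replicate number was possible because the numbers only name oocytes within a group; title prefixes are shared between groups of one age, and differences within them were computed. Of 380 named-gene values, 380 moved by less than the spread between oocytes with DESeq2 size factors and 380 without a filter. So did all 372 that remain without mitochondrially encoded genes. With TPM 45 moved, and without the 4 oocytes 17. With 1 oocyte left out, 9 of 2460 values moved. Leaving out 1 oocyte shifts a group mean by only part of the spread, so this limit could hardly be passed. That low count therefore does not show stable values. Without MSC-IVM-MII 12m oocyte 1, Hmgcs1 with co-culture at 12m went from −1.608 to 0.259. Without IVM-MII 6wk oocyte 1, Mos by age in IVM-MII oocytes went from −3.971 to −1.573. Genes named because their oocytes did not overlap keep their direction by that choice when an oocyte is left out, and partly by it under other alternatives. Named list members whose oocytes overlapped had no called direction, and some changed sign with an oocyte left out. Of 231 list values, 14 moved and 13 reversed without the 4 oocytes, 3 moved and 1 reversed with TPM, 5 moved and 1 reversed without a filter, and 25 list results reversed under at least 1 setting.

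Without the 4 oocytes that stood apart, maturation at 6wk gave −0.12 for deadenylation, −0.12 for DNA methylation and −1.13 for proteasome genes. Age gave 0.37 for oocyte, −0.056 for PI3K-AKT-mTOR and −0.23 for glycolysis genes in GV oocytes, and for mitochondrially encoded mRNAs −0.26 in IVM-MII and −0.024 in co-cultured oocytes. The age difference in the maturation effect was 0.64 for cohesin, 0.58 for deadenylation, −0.21 for oxidative phosphorylation, 0.093 for DNA methylation and 0.33 for PI3K-AKT-mTOR genes. The age difference in the co-culture effect was 0.49 for mesenchymal markers. The correlation of age differences between GV and co-cultured oocytes was −0.013, and that of the co-culture differences at 6wk and 12m was 0.176. The latter was −0.032 with TPM and −0.033 within title prefixes. That of age in GV oocytes with co-culture at 12m (0.004) was −0.182 without the 4 oocytes, −0.001 without a filter, −0.045 with TPM and −0.003 with only the groups compared. TPM gave −0.11 for PI3K-AKT-mTOR genes by age in GV oocytes, and no filter gave −0.27 for mesenchymal markers in the age difference of the maturation effect. The cause was not tested for any of these.

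Detected genes in IVM-MII minus GV oocytes were −3986 at 6wk and −4380.3 at 12m with a limit of 1 count. With limits of 5 and 10 they were −2417 and −1697 at 6wk and −3311 and −2529.7 at 12m. Why the difference was smaller at higher limits was not tested.

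With each oocyte left out in turn, maturation at 6wk ranged from −0.125 to 1.015 for deadenylation, −0.127 to 0.724 for DNA methylation and −2.28 to −1.14 for proteasome genes, and maturation at 12m from −4.36 to −3.74 for ribosomal proteins. Age in GV oocytes ranged from −0.387 to 0.362 for oocyte, −0.25 to 0.631 for oxidative phosphorylation, −0.078 to 0.847 for mitochondrially encoded, −0.048 to 0.757 for PI3K-AKT-mTOR and −0.236 to 0.532 for glycolysis genes. Age ranged from −0.257 to 0.875 for mitochondrially encoded mRNAs in IVM-MII oocytes, and in co-cultured oocytes from −0.034 to 0.639 for ribosomal proteins and −0.143 to 0.485 for TGF-beta genes. Co-culture at 12m ranged from −0.01 to 0.656 for TGF-beta genes and −1.093 to 0.011 for mesenchymal markers. Co-culture at 6wk ranged from −1.103 to 0.293 for mitochondrially encoded, −0.649 to 0.218 for ribosomal protein and −0.413 to 0.049 for proteasome genes. The age difference in the maturation effect ranged from −1.131 to 0.166 for cohesin, −0.841 to 0.148 for deadenylation and −0.759 to 0.003 for DNA methylation genes, and that in the co-culture effect from −0.195 to 1.093 for mitochondrially encoded and −0.015 to 0.411 for antioxidant genes. The correlation of the co-culture differences ranged from −0.079 to 0.125, and that of age in GV oocytes with co-culture at 12m from −0.133 to 0.109. The cause was not tested.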

Other observations

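The gene families in this part, the test of the mitochondrial share, the count of list medians of one sign between title prefixes, the test of oocyte gene levels in GV 12m oocyte 3 and the test of position between GV and metaphase II were chosen after the data were seen; the other tests were set before their result. Among 32 families examined, those outside the fixed lists that were lower after maturation included mitochondrial ribosomal proteins, with medians of −2.60 at 6wk (69 of 79 lower) and −2.64 at 12m (71 of 79). Timm and Tomm genes, which import proteins into mitochondria, had −2.36 (21 of 24 lower) and −2.78 (20 of 24). Tubulins had −2.74 (14 of 19 lower) and −2.07 (16 of 19), and dynein subunits −3.71 (12 of 15) and −2.38 (11 of 15). Subunits of the chaperonin TRiC, which folds actin and tubulin, were lower for 8 of 8 at 6wk (−2.37, and −1.54 without IVM-MII 6wk oocyte 1) and for 6 of 8 at 12m (−1.37).

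Some of these families also differed between metaphase II groups, where 1 group enters several of the values. With co-culture at 12m, histone genes were lower for 31 of 36 (median −0.90, and −1.37 and −0.35 without IVM-MII 12m oocytes 1 and 3 in turn) and dynein subunits for 13 of 15 (−1.03, −1.15 to −0.89). Ragulator subunits, which anchor mTORC1 to lysosomes, were lower for 5 of 5 (−1.25, and −0.58 without MSC-IVM-MII 12m oocyte 2). With co-culture at 6wk tubulins were higher for 15 of 19 (0.62, 0.47 to 0.80 with an oocyte left out), while at 12m their median was −0.24 (percentile 26.07, and −0.46, −0.16 and −0.645 without IVM-MII 12m oocyte 1, MSC-IVM-MII 12m oocyte 1 and MSC-IVM-MII 12m oocyte 3 in turn, −0.13 with DESeq2 size factors and −0.07 with TPM). By age, IVM-MII oocytes of 12m had higher histone genes (27 of 36, median 0.95, and 0.50 without IVM-MII 12m oocyte 3), and co-cultured oocytes of 12m had lower tubulins (14 of 19, −0.72, and −0.40 without MSC-IVM-MII 12m oocyte 1). Many histone mRNAs end in a stem-loop in place of a poly(A) tail, and SMART-seq2 copies polyadenylated RNA. The histone values may therefore cover only part of these transcripts. The IVM-MII 12m oocytes enter both histone values, and the MSC-IVM-MII 6wk oocytes enter both the tubulin value with co-culture at 6wk and that by age. The other family medians given here kept their direction and moved by less than 1.5 times with DESeq2 size factors and with TPM.

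Ribosomal protein and oxidative phosphorylation mRNAs were far lower in IVM-MII than in GV oocytes at both ages. Gene length was argued against as the whole cause, since the lowest of 10000 random lists matched on length and expression had a median of −2.59 for ribosomal proteins at 6wk against −4.15 observed (−2.12 against −4.26 at 12m), and −2.41 and −1.81 for oxidative phosphorylation against −3.61 and −2.85. A larger share of counts taken by mitochondrial mRNAs was argued against as well, since from the GV oocyte with the lowest share to the IVM-MII oocyte with the highest the share left to other genes differed by −0.17 (log2) at 6wk and −0.21 at 12m, far less than these medians. SMART-seq2 primes on poly(A) tails, so shorter tails in metaphase II oocytes may give lower counts without loss of the transcript. These data hold no tail lengths, and that explanation and degradation stay open as hypotheses. Whether spinning down the nucleus affected the 2 stages differently was not tested either.

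In GV 12m oocyte 3 the summed cumulus and granulosa cell markers were high. Of the 29 markers 16 were higher there than in the other 5 GV oocytes. Not all were raised. Cyp19a1 was at 16.2 CPM (19.8 to 33.0 CPM in the other 5), Cyp11a1 at 0.15 CPM and Foxl2 at 0.3 CPM, and Amh had no count. A second list of 15 genes of somatic ovarian cells, fixed before it was read, summed to 275 CPM in this oocyte. That was 4.73 times the highest of the other 5 GV oocytes (58.2 CPM), although Nap1l5 alone gave 165 of it. Of the 15 genes 8 were highest here. RNA of attached granulosa or cumulus cells may therefore be a source, with Inhbb at 365 and Fst at 234 CPM. Malat1, an RNA of many cell types, was at 1301 CPM (9.68 to 50.35 CPM in the other 5) and does not tell the source. Vim was at 8.33 and Tmsb4x at 0.61 CPM, and Actb at 208 CPM lay within the range of the other 5 (124 to 233 CPM), so whether whole cells or part of their RNA were carried over stays open. A cell of another type in place of an oocyte was argued against by a median of 9.07 log2 CPM over the oocyte genes, within the range of the other GV oocytes, although their sum (25959.6 CPM) lay below that of the other 5 (51144 to 108660.1 CPM) and Gdf9 (1562 CPM) and Zp3 (2067 CPM) were the lowest of the 6, so a library mixed from an oocyte and other cells stays open; no biological explanation was tested.

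The 6wk metaphase II oocytes of title prefix Y01 differed from those of Y03 in both culture groups, with high Mos, Gdf9, Plat, Bub1b (472 and 261 CPM, against at most 52.0 in the other 10 metaphase II oocytes) and H1foo. A gene length trend was argued against as the whole cause, since the Y01 minus Y03 differences in the 2 groups correlated at 0.534 across genes and at 0.489 with the trend removed. An unfinished change of the whole profile was argued against for IVM-MII oocyte 1, which lay at 1.02 on a scale from GV 12m (0) to IVM-MII 12m (1), while MSC-IVM-MII oocyte 1 lay at 0.834, below the other 6wk metaphase II oocytes (0.895 to 0.998). Single transcripts went both ways. In both oocytes Mos, Gdf9 and H1foo lay within the GV range (546 to 1973, 1562 to 18966 and 6986 to 26737 CPM). H1foo reached 12252 CPM in the other metaphase II oocytes, so it sets the Y01 oocytes apart less clearly. Bub1b lay above every GV oocyte in both (highest GV value 234 CPM), as did Smc3 (947 and 600 CPM, highest GV value 226 CPM). Plat lay above every GV oocyte in IVM-MII oocyte 1 only (4078 CPM, highest GV value 2060 CPM). Their mitochondrial shares (3.22% and 3.03%) also lay within that of GV oocytes (0.92% to 3.70%). Zp3 (115 and 473 CPM) and Cdk1 (0.23 and 7.39 CPM) lay below every GV oocyte. The scale therefore speaks only for the profile as a whole. A batch shared by all Y01 oocytes could not be told apart from a difference between oocytes, since the Y01 minus Y03 difference in GV oocytes correlated with that in IVM-MII oocytes at 0.387 and with that in MSC-IVM-MII oocytes at 0.243, on either side of the bound of 0.3, and rested on GV 6wk oocyte 2 (0.493 and 0.321, against 0.138 and 0.071 for GV 6wk oocyte 1), while 14 of 21 list medians of Y01 minus Y03 had the same sign in all 3 groups, as a shared batch would give (mitochondrially encoded −1.36, −1.86 and −1.85; PI3K-AKT-mTOR 0.965, 2.19 and 1.27). Differences between animals or in the stage of single oocytes stay open and untested.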
